A study of Mus musculus with 6 samples.

How the data were processed

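Total RNA of testes from 12-week-old mice was extracted with RNeasy columns, made into biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels' protocols. There were 6 arrays, 3 labelled jsd and 3 labelled SCARKO-jsd, numbered 1 to 3 in each group by the labels. The series' design gives 3 mice for each genotype. The labels do not say which mouse each RNA came from, so p-values measure the spread among these samples. The deposited values are log2 expression per probe set, made by the authors with RMA in the affy package, per the submitters' processing notes, and the package version is not given in the sources used here. RMA corrects background, sets the arrays to a shared distribution and summarises the probes of each probe set. The values ran from 2.58 to 14.84 with 0 missing, which is a log2 range, and were not centred by gene. Array medians lay between 6.26 in SCARKO-jsd 2 and 6.41, so SCARKO-jsd 2 was slightly off the shared distribution. Quantile normalization pulls all arrays to the same overall brightness, so a shift of most transcripts in one direction cannot be seen in such values.

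The table held 45101 probe sets, 64 of them controls. GEO's platform annotation, which can be old, gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211, the controls included. Symbols were compared with a RefSeq table (GRCm38.p6) through the gene ID, which was found for 34741 probe sets, and 0 symbols needed updating. That table was used only for names, chromosomes and which genes neighbour each other, and no coordinates are given because no build is named for the array values. A probe set with several symbols named no gene. For each of the 18193 genes, the probe set with the highest mean over the 6 arrays was used, and the genes in the lowest 40% of that mean (log2 expression up to 6.64) were left out, which left 10916.

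Each gene was tested with limma 3.58.1 (lmFit and eBayes, no trend) in R 4.3.3, with genotype as the only term, two-sided, and adjusted by Benjamini-Hochberg with a threshold of 0.05. Gene lists, 22 in number, were drawn up before the data were examined, as were this design, the alternatives and the rule for named genes. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The named genes are Utp14b, 1 gene that is not reported here, the 12 largest rises and the 12 largest falls among called genes whose arrays do not overlap between the groups, and up to 4 members of each list with the smallest p. Genes named outside this rule are said to be chosen after their values were seen. Where a gene had a second bright probe set of the opposite sign, as Jam2, Dnmt3b and Fcgr1 did among the named genes, the brightest was kept.

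The alternatives were no filter on dim genes, a filter on the lowest 60%, every probe set by itself, the mean of a gene's probe sets, median centring, a further quantile normalization, eBayes with trend and robust, arrayWeights, a replicate block, adjusted p thresholds of 0.01 and 0.1, and each array left out in turn. Same-numbered arrays of the groups were not taken as pairs. No arrays held identical values. Changed genes per chromosome were compared by Fisher's exact test, and 134 families of genes sharing the letters of their symbol, with at least 10 tested members each, were tested with camera.

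The fit was tested on simulated data for the comparison of SCARKO-jsd with jsd, with the real means and spreads of the 10916 genes and changes of known size. It called 97.1% of 68 genes changed 4-fold, 80.3% of 66 changed 2-fold and 60.6% of 66 changed 1.5-fold, all in the right direction, with 12 false calls, 6.74% of all calls. A list of 12 genes lowered by 0.5 log2 units was called by camera and 0 of 19 unchanged lists were. The simulated noise was independent between genes, whereas the correlations estimated within the real lists ran from 0.046 to 0.885. The simulation therefore cannot show how often camera falsely calls lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. For arrays, the number of arrays and the signal over background limit the precision.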

Results

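RNA from whole testes of 12-week-old mice was measured on 6 Affymetrix arrays, 3 from jsd mice and 3 from SCARKO-jsd mice. The jsd (juvenile spermatogonial depletion) mutation lies in Utp14b and leaves the adult seminiferous tubules with Sertoli cells and spermatogonia but few later germ cells. SCARKO-jsd mice also carry a conditional knockout in Sertoli cells, the somatic cells that support the germ line. The comparison asks which testis transcripts differ with that knockout in a testis with few germ cells. Values were log2 expression after RMA, between 2.58 and 14.84, and every difference is SCARKO-jsd minus jsd. The number of arrays, 3 per group, limits the precision, and the median SE of a log2 fold change was 0.11 over the 10916 genes tested.

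Several androgen-dependent genes of Sertoli cells fell in SCARKO-jsd testes, while a mixed set of other genes, some of them dim in jsd testes, rose. Rhox5, an X-linked homeobox gene that androgen switches on in Sertoli cells, was 10.14 ± 0.36 in jsd and 5.80 ± 0.34 in SCARKO-jsd testes (log2 expression, SD, n = 3), 20.4-fold lower. Corin, a membrane serine protease, was 8.27-fold lower and Drd4, a dopamine receptor, 4.75-fold lower. In the other direction, the stress kinase gene Mapk13 was 5.78 ± 0.35 in jsd and 8.87 ± 0.19 in SCARKO-jsd testes (log2 expression, SD, n = 3), 8.54-fold higher. Sycp3, a protein of meiotic chromosomes, also rose, 2.48-fold. The lower of the group means of Rhox5, Corin and Mapk13 lay under the limit for dim genes (6.64), so the size of their folds is uncertain.

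Utp14b, mutated in both groups, did not pass the test. Its log2 expression was 7.44, 7.68 and 7.34 in jsd 1, 2 and 3 and 7.23, 7.87 and 7.59 in SCARKO-jsd 1, 2 and 3. The difference was 0.078 ± 0.17 (SE), with a limma Benjamini-Hochberg adjusted p of 0.850, and it turned to -0.078 without SCARKO-jsd 2. Rhox5 was lower in each array labelled SCARKO-jsd (5.44, 6.11 and 5.84) than in each array labelled jsd (10.26, 10.43 and 9.74).

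In all, 390 of the 10916 genes differed by limma at a Benjamini-Hochberg adjusted p under 0.05, 194 of them higher and 196 lower in SCARKO-jsd testes. At least 1.5-fold changes numbered 296, with 156 rises and 140 falls, and at least 4-fold changes numbered 10 rises and 6 falls. The arrays of the groups did not overlap for any of the 390 genes, nor for 24.6% of all genes tested, where chance gives 10%. At an unadjusted p under 0.05 there were 1960 genes, against 546 expected by chance. Setting jsd 1, jsd 2 and SCARKO-jsd 2 against the other arrays gave 1182 such genes, the most of any other split into 3 and 3. The figure of 546 thus leaves out structure shared among the arrays, though that split also holds part of the genotype difference. The count of 390 called genes fell to 78 without jsd 1, 119 without jsd 2, 239 without jsd 3 and 141 without SCARKO-jsd 3. It rose to 768, with 300 higher and 468 lower, without SCARKO-jsd 2, where all 390 genes kept their call, and 72 of the 390 were called with any 1 array left out.

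**Figure D1:**
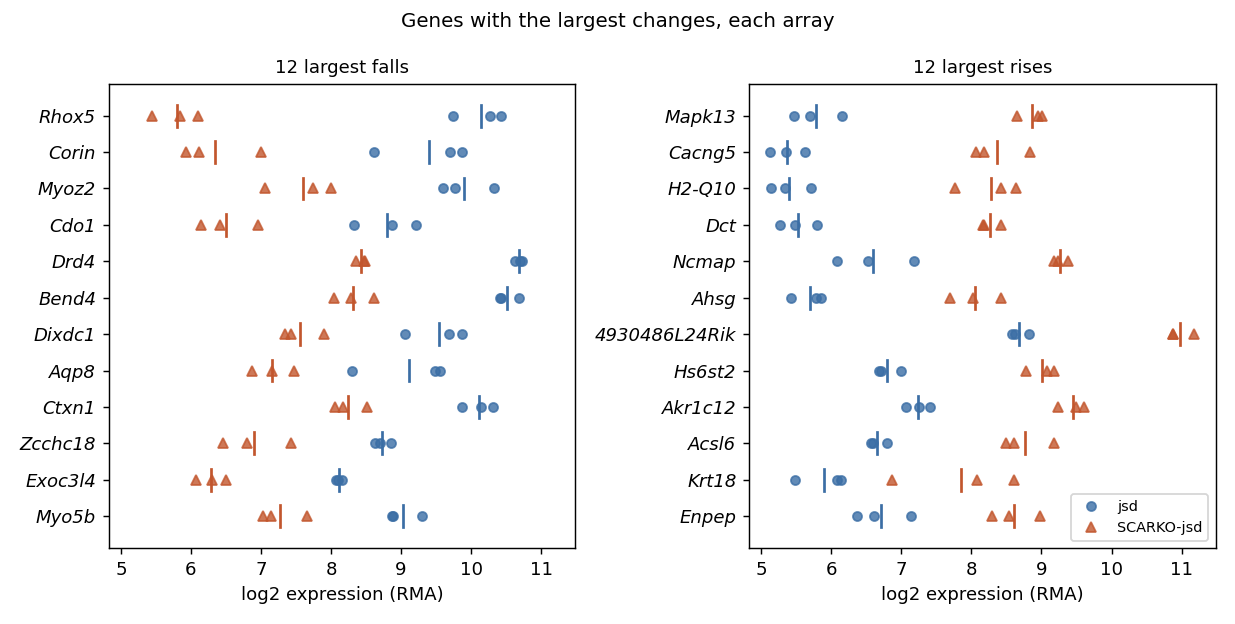
Log2 expression (RMA, x axis) of the 12 genes with the largest falls and the 12 with the largest rises (y axis), one point per array, circles for jsd and triangles for SCARKO-jsd, with vertical bars at the group means. For Rhox5 the jsd mean is 10.14 and the SCARKO-jsd mean 5.80, and for Mapk13 the means are 5.78 and 8.87; in each gene drawn, the arrays of the groups do not overlap.

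After Rhox5 and Corin, the largest falls were those of Myoz2, a protein of the muscle Z-disc (log2 fold change -2.30 ± 0.27 SE), Cdo1, which oxidises cysteine (-2.30 ± 0.27), Drd4 (-2.25 ± 0.085) and Bend4 (-2.20 ± 0.16). Dixdc1, a regulator of Wnt signalling, followed at -1.98 ± 0.23, and the water channel gene Aqp8 at -1.95 ± 0.33. Ctxn1, Zcchc18, Exoc3l4 and the motor protein gene Myo5b had log2 fold changes of -1.86, -1.83, -1.83 and -1.74. The SCARKO-jsd means of Cdo1 (6.50) and Exoc3l4 (6.29) lay under the dim limit (6.64), so the size of their falls is uncertain. A second bright probe set gave -1.69 for Drd4 and -1.84 for Bend4. Other probe sets, all dim, gave -0.31, -0.43 and -0.76 for Dixdc1 and -1.38 and -0.25 for Myo5b, and with the mean of probe sets Dixdc1 was at -0.87 and Myo5b at -1.12, both still called. Calls ended for Corin and Zcchc18 without jsd 1 (limma, Benjamini-Hochberg adjusted p = 0.0532 for both) and for Aqp8 without jsd 1, jsd 2, SCARKO-jsd 1 or SCARKO-jsd 3 (adjusted p up to 0.102).

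The largest rises after Mapk13 were those of Cacng5, of the calcium channel gamma subunit family (2.99 ± 0.22 SE), H2-Q10, a secreted class I histocompatibility protein (2.88 ± 0.24), Dct, an enzyme of melanin synthesis (2.74 ± 0.15), and the myelin protein gene Ncmap (2.67 ± 0.25). Ahsg, which encodes the plasma protein fetuin A, was 5.69 ± 0.23 in jsd and 8.04 ± 0.36 in SCARKO-jsd testes (log2 expression, SD, n = 3). 4930486L24Rik rose by 2.31, Hs6st2, a heparan sulfate sulfotransferase, by 2.22, Akr1c12, an aldo-keto reductase, by 2.21 and Acsl6, an acyl-CoA synthetase, by 2.11 on the log2 scale. Akr1c13, a close relative of Akr1c12 chosen after its value was seen, rose by 1.82, and probes of such near-identical genes can share signal, so which of them changed is uncertain. Krt18 (1.95 ± 0.41), a keratin of immature Sertoli cells, and Enpep, which encodes aminopeptidase A (1.90 ± 0.23), completed the 12. The jsd means of Cacng5, H2-Q10, Dct, Ncmap, Ahsg and Krt18 lay, like that of Mapk13, under the limit for dim genes (6.64). The size and order of these rises are therefore uncertain. Other probe sets, all dim, gave 0.16 for Cacng5, 0.98, 0.34 and 0.10 for Hs6st2 and 0.43 for Acsl6. With the mean of probe sets Acsl6 was at 1.27, still called, and the call of Krt18, which has 1 probe set, ended (limma, Benjamini-Hochberg adjusted p = 0.0558), as it did with trend and robust (0.0717), no filter on dim genes (0.0540) or a further quantile normalization (0.0518). The call of Krt18 also ended without jsd 1, jsd 2, jsd 3 or SCARKO-jsd 3 (limma, Benjamini-Hochberg adjusted p up to 0.174), and that of Enpep without jsd 1 (adjusted p = 0.0532).

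SCARKO-jsd 2 stood apart from the other arrays. Its correlation with them across genes was 0.952 to 0.973, against up to 0.994 among the others, where genes are not independent replicates. Probe sets at the 3' end of beta-actin exceeded those at the 5' end by 1.66 log2 units in SCARKO-jsd 2, against 0.70 to 0.98 in the other 5 arrays. For Gapdh the gap was 0.64 in that array and -0.28 to -0.10 in the others, and for pyruvate carboxylase 3.45 against 2.82 to 3.15. For the transferrin receptor it was 1.78, within the 1.68 to 2.10 of the others. The labels give no scan date or batch, so no such term could be fitted.

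**Figure D2:**
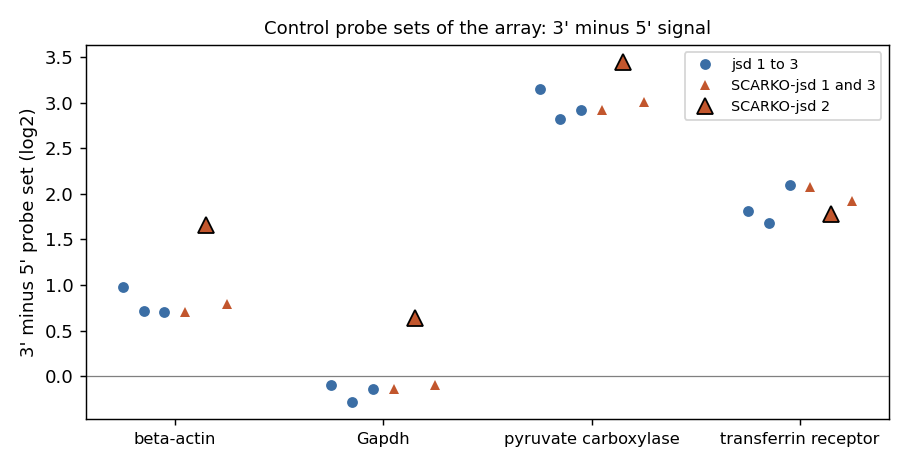
Log2 signal of the 3' probe set minus that of the 5' probe set (y axis) for 4 control transcripts (x axis), one point per array, circles for jsd, triangles for SCARKO-jsd and a large outlined triangle for SCARKO-jsd 2. SCARKO-jsd 2 lies at 1.66 for beta-actin and 0.64 for Gapdh, above the other 5 arrays, and at 1.78 for the transferrin receptor, among them.

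Androgen-dependent genes of Sertoli cells fell as a group. Of 12 tested members, 6 fell and 6 did not pass the test, with a median log2 fold change of -0.49. Rhox5, Corin, Drd4 and Tpd52l1 (-0.48 ± 0.08 SE) had the smallest p, and the protease inhibitors Eppin (-0.50) and Serpina5 (-0.38) lay, by limma at a Benjamini-Hochberg adjusted p = 0.0682 and 0.0664, outside the threshold, Eppin passing without jsd 3 (0.0411). Gpd1 (-0.74) and, chosen after their values were seen, Slc38a5 (-0.26), Tubb3 (-0.04) and Cldn3 (-0.02) did not pass either. The fall was thus not shared by all members. Adjusted over the list alone, 10 members fell. The direction of this list was known when it was drawn up. It differed from the other genes by camera (Benjamini-Hochberg adjusted p = 3.28e-12), with an adjusted p = 0.198 with an estimated correlation, and its adjusted p lay between 7.42e-15 and 0.198 over 18 alternatives. The call of Tpd52l1 ended without jsd 1, jsd 2, jsd 3 or SCARKO-jsd 3 (limma, adjusted p up to 0.117) and with median centring (0.126), and the list was called with any 1 array left out, SCARKO-jsd 2 included (adjusted p up to 4.44e-10).

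**Figure D3:**
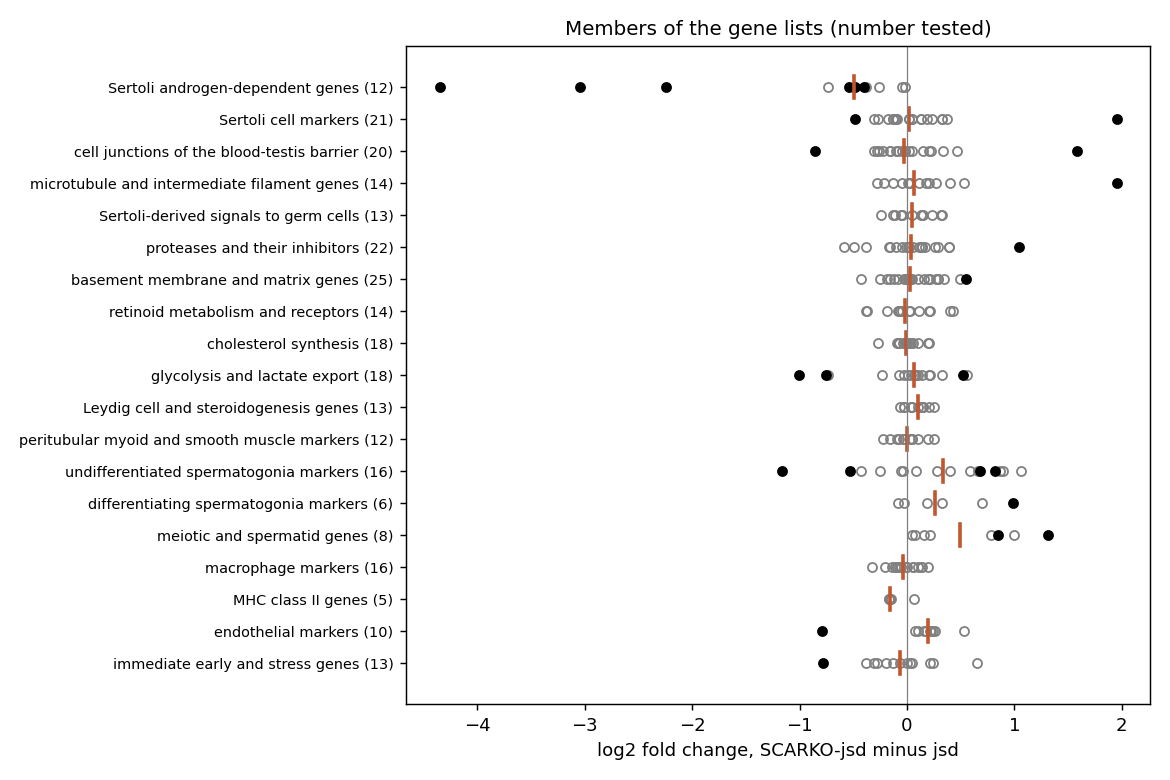
Log2 fold change, SCARKO-jsd minus jsd (x axis), of each tested member of the 19 gene lists (y axis, number of members tested in brackets), filled where the gene passed the test over all genes and open where it did not, with a vertical bar at the list's median. The androgen-dependent list has its median at -0.49 and the meiotic list at 0.50.

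Most general markers of Sertoli cells did not pass the test. Among 21 tested, Krt18 rose, Wt1, a transcription factor that maintains Sertoli cell identity, fell by 0.48 on the log2 scale, and 19 did not pass the test, with a median log2 fold change of 0.02. Adjusted over the list alone, 2 rose and 1 fell. Inha, a subunit of inhibin, was higher by 0.33 and Amh, a hormone of immature Sertoli cells, by 0.33, neither of them past the threshold (limma, Benjamini-Hochberg adjusted p = 0.0792 and 0.134). The call of Wt1 ended without any array but SCARKO-jsd 2 (adjusted p up to 0.187) and with median centring (0.151). Without SCARKO-jsd 2, Inha (0.0493) and Espn, chosen after its value was seen (-0.48, 0.0260), passed.

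At the junctions of the blood-testis barrier, 1 of 20 tested genes fell, 1 rose and 18 did not pass, the same counts as adjusted over the list alone. Cdh2, which encodes N-cadherin, fell from 10.36 ± 0.13 in jsd to 9.51 ± 0.06 in SCARKO-jsd testes (log2 expression, SD, n = 3), 1.81-fold. Cxadr, an adhesion protein of tight junctions, rose by 1.59 ± 0.29 (SE) on its brightest probe set, while its other bright probe set gave 0.15. Ocln had a log2 fold change of 0.47 and Jam2 of -0.28 (limma, Benjamini-Hochberg adjusted p = 0.192 and 0.164), and the other bright probe sets of Jam2 gave -1.95, -0.46, -0.39 and 0.21. Cdh2 was called with any 1 array left out, and the call of Cxadr ended without jsd 1, jsd 2, SCARKO-jsd 1 or SCARKO-jsd 3 (adjusted p up to 0.113). Espn passed without SCARKO-jsd 2 here too (0.0260).

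Other somatic lists held single called genes and did not pass as lists. Serpina3n, a serine protease inhibitor, rose by 1.05 ± 0.15 (SE) among 22 proteases and inhibitors, where 21 did not pass, and Mmp14, a membrane-bound matrix protease, had a log2 fold change of -0.59, outside the threshold (limma, Benjamini-Hochberg adjusted p = 0.0524). Col4a1, a chain of basement membrane collagen, rose by 0.55 ± 0.10 among 25 matrix genes, where 24 did not pass, and its partner Col4a2 was higher by 0.49 (adjusted p = 0.0615). Adjusted over the list alone, 3 rose and 3 fell in the first list and 2 rose in the second. Among 14 microtubule and filament genes Krt18 rose, and 13 did not pass, with the same counts adjusted over the list alone. The call of Serpina3n ended without jsd 1 or jsd 2 (adjusted p up to 0.0724), and that of Col4a1 without any array but SCARKO-jsd 2 (up to 0.121), with the mean of probe sets (0.115) and with median centring (0.0607). Mmp14 passed without SCARKO-jsd 1 (0.0405) or SCARKO-jsd 2 (0.0478).

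In glucose metabolism, 2 genes fell, 1 rose and 15 did not pass of 18 tested, the same counts as adjusted over the list alone. Slc2a3, a glucose transporter, fell by 1.01 ± 0.16 (SE on the log2 scale), Pfkl, the liver-type phosphofructokinase, fell by 0.75 ± 0.14, and Pdk1, a kinase that restrains pyruvate oxidation, rose by 0.52 ± 0.11, with 0.46, 0.44 and 0.15 on its other bright probe sets. Gpd1 had a log2 fold change of -0.74, outside the threshold (limma, Benjamini-Hochberg adjusted p = 0.187). The calls of Slc2a3 and Pfkl ended without jsd 1, jsd 2, jsd 3 or SCARKO-jsd 3 (adjusted p up to 0.105 and 0.151), and that of Pdk1 without any array but SCARKO-jsd 2 (up to 0.194), with the mean of probe sets (0.143) and with no filter on dim genes (0.0578). With median centring the calls of Pfkl (0.0752) and Pdk1 (0.103) ended.

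No tested gene passed the threshold by limma among 13 signals from Sertoli to germ cells, 14 retinoid genes, 18 of cholesterol synthesis, 13 of Leydig cells, 12 of peritubular myoid cells, 16 of macrophages and 5 of MHC class II. At an unadjusted p under 0.05 these lists held 1, 2, 1, 0, 0, 1 and 0 genes in that order, and 0 in each when adjusted over the list alone. Hsd17b3, which makes testosterone in Leydig cells, was higher by 0.25 ± 0.13 (SE) and the smooth muscle gene Tagln by 0.20 ± 0.09. Igf1 had a log2 fold change of -0.24 ± 0.12 and the macrophage gene Fcer1g of -0.33 ± 0.08. In this order, their limma Benjamini-Hochberg adjusted p values were 0.350, 0.293, 0.340 and 0.0814. Without SCARKO-jsd 2, 2 of the signals passed, Inha (0.35, adjusted p = 0.0493) and Wnt5a (0.89, 0.0266), as did the retinoid gene Cyp26a1 (-0.56, 0.0441). With all arrays Wnt5a was at 0.32 and Cyp26a1 at -0.38, both chosen after their values were seen.

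Some germ cell genes rose. Among 8 tested genes of meiosis and spermatids, Sycp3, of the synaptonemal complex, rose from 6.85 ± 0.21 to 8.16 ± 0.16 (log2 expression, SD, n = 3), Meig1 rose by 0.84 ± 0.14 (SE), and 6 did not pass, with a list median of 0.50. Adjusted over the list alone, 3 rose, and Sycp1 was higher by 1.001 ± 0.23 (limma, Benjamini-Hochberg adjusted p = 0.0642). The list has 28 measured members, and those not tested were dim. With no filter on dim genes the list median was 0.15 (camera, adjusted p = 0.0169), and over all alternatives it lay between 0.15 and 0.72. The list differed from the other genes by camera (adjusted p = 0.0109), with an adjusted p = 0.955 with an estimated correlation, over a range of 0.000147 to 0.955 in 17 alternatives. Without SCARKO-jsd 2, whose germ cell list medians lay 0.29 to 0.36 above the other SCARKO-jsd arrays, the list median was 0.40 (camera, adjusted p = 0.0182). Sycp3 was called with any 1 array left out, and the call of Meig1 ended without jsd 1, jsd 2 or SCARKO-jsd 1 (limma, adjusted p up to 0.0969). Sycp1 passed without SCARKO-jsd 2 (0.0468) and Smc1b without SCARKO-jsd 1 (0.0219).

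Markers of spermatogonia went both ways, in RNA of whole testes that does not show which cells changed. Among 16 markers of undifferentiated spermatogonia, Uchl1 rose by 0.68 ± 0.11 (SE) and Dazl, an RNA-binding protein of germ cells, by 0.82 ± 0.16, while Id4, an inhibitor of helix-loop-helix factors found in spermatogonial stem cells, fell by 1.17 ± 0.18 and Epcam fell by 0.53 ± 0.10. The other 12 did not pass, and adjusted over the list alone 8 rose and 3 fell. Stra8, which retinoic acid induces before meiosis, rose by 0.99 ± 0.19 among 6 markers of differentiating spermatogonia, of which 5 did not pass and 2 rose when adjusted over the list alone. Sohlh2 was higher by 0.70 ± 0.23 (limma, Benjamini-Hochberg adjusted p = 0.161), with a jsd mean (6.637) just under the dim limit (6.642). The other bright probe set of Epcam gave -0.013, and with the mean of its probe sets the fold change was -0.27 and the call ended (limma, adjusted p = 0.202). Calls ended for Uchl1 and Id4 without jsd 1, jsd 2 or SCARKO-jsd 3 (adjusted p up to 0.0980 and 0.0958), for Dazl and Stra8 also without jsd 3 (up to 0.163 and 0.154), and for Epcam without any array but SCARKO-jsd 2 (up to 0.135) and with median centring (0.112). Sohlh2 passed without SCARKO-jsd 1 (0.0485), and Etv5 (-0.48), Gfra1 (0.37) and Sohlh1 (0.75), chosen after their values were seen, passed without SCARKO-jsd 2.

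Of the remaining lists, Kdr, a receptor for vascular endothelial growth factor, fell by 0.79 ± 0.16 (SE) among 10 endothelial markers, where 9 did not pass and Vwf was higher by 0.53. Hspb1, a small heat shock protein, fell by 0.79 ± 0.10 among 13 immediate early and stress genes, of which 12 did not pass. Both counts were the same when adjusted over the list alone. The call of Kdr ended without any array but SCARKO-jsd 2 (limma, Benjamini-Hochberg adjusted p up to 0.175) and with median centring (0.0906), and that of Hspb1 ended without jsd 1 (0.0548). Dnajb1 passed without SCARKO-jsd 2 (-0.47, 0.0468). Alas2, the heme synthesis enzyme of red cells, was the only tested member of the red blood cell list and fell by 1.21 ± 0.10. Hba-a1, Slc4a1 and Epb42 of that list were dim, so the fall of Alas2 alone does not show a change in red cells. Cd4 was the only tested member of the T, B and mast cell list (-0.03 ± 0.08). No epididymal or rete testis marker was tested, as 8 of the 10 were dim and the others had no probe set of their own.

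Among the 19 lists with at least 3 tested members, 2 passed camera and 17 did not, with Benjamini-Hochberg adjusted p values from 0.268 to 0.974 for the 17. The median, the mean and the test did not share a sign in 6 of them: Sertoli cell markers, junctions, proteases, retinoid genes, glycolysis and peritubular myoid markers. With an estimated correlation camera passed 0 lists at an adjusted p under 0.05 and 1 at an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance one way, passed 1, the androgen-dependent genes (adjusted p = 0.00331). Its version for changes in either direction passed further lists, such as glycolysis (fry, adjusted p = 0.000185) and junctions (0.000423). Other lists did not pass it, such as the Leydig cell genes (0.741).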

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

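The tests of 5' signal loss and of a wrong label were chosen only after the array was seen to stand apart.

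In the control probe sets, which no comparison used, SCARKO-jsd 2 showed a 3' minus 5' gap of 1.66 log2 units for beta-actin and 0.64 for Gapdh, above all 3 jsd arrays and the other SCARKO-jsd arrays. In that array 171 genes lay over 1 log2 unit below the mean of the other SCARKO-jsd arrays and 35 above, against 25 genes that far apart between SCARKO-jsd 1 and 3. Sfpq, a splicing factor gene, read 6.39 there and 11.02 to 11.76 elsewhere, Luc7l2, another splicing gene, read 7.45 against 11.22 to 12.18, and all 8 measured nuclear-retained RNAs, Malat1 and Neat1 among them, were lower, by a median of -0.80, in a list drawn up after the array was seen.

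A change in whole-gene expression in that animal was argued against by 2687 pairs of probe sets of one gene, whose deviations differed with an SD of 0.612 against at most 0.372 in any other array. Their correlation was 0.229, against 0.293 and 0.366 in the other SCARKO-jsd arrays and 0.507 to 0.534 in jsd arrays. Each array was set against the mean of the other arrays of its group. The values for SCARKO-jsd 1 and 3 thus also carry the deviation of SCARKO-jsd 2 and are not independent of it. The jsd arrays, free of this, had SDs of 0.160 to 0.202. Another mix of cell types would also move both probe sets of a gene, and the largest median deviation of a cell type list was 0.358 (SD 0.34 over 8 meiotic genes), so neither accounts for the whole pattern. A wrong label was argued against by Rhox5 and Drd4, which lay at least 2.14 log2 units below the lowest jsd array. A loss of 5' signal, from RNA integrity or labelling, is a candidate explanation in keeping with the Gapdh gap of 0.64, found and tested on the same array, and changes in transcript forms or RNA export in that animal were not tested.

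Of 3487 probe sets with no listed gene, 4 changed by limma at a Benjamini-Hochberg adjusted p under 0.05 among 27059 probe sets tested, 3 up and 1 down. The first rose from 5.79 ± 0.24 to 8.31 ± 0.27 (log2 expression, SD, n = 3), by 2.53. Another rose by 0.74, and the one that fell had a log2 fold change of -0.90.

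With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 390 changed genes, and 1 split, the real one, gave as many, where the highest other split gave 1. For changes of at least 1.5-fold these were 296 and 1, again with 1 split as large. For gene lists the real split gave 2 and the highest other, jsd 1 with SCARKO-jsd 1 and SCARKO-jsd 2, gave 10, and 8 of the 10 splits gave at least 2. This may reflect a structure among the samples, but camera's preset correlation was below the estimated ones, and the cause was not tested. The androgen-dependent list was under 0.05 in 6 of the 9 other splits, each of which still holds part of the genotype difference, with a lowest camera Benjamini-Hochberg adjusted p of 0.00107 against 3.28e-12 in the real split. The meiotic list was under 0.05 in 2 of the 9, with a lowest adjusted p of 0.0380 against 0.0109.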

How the results depend on the processing

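All alternatives here were planned. Every one of the 390 genes kept its direction under both other scalings. Since the groups' arrays did not overlap for these genes, leaving out or weighting arrays could not turn it. Named genes that passed lost their call in 39 of 354 fits under other settings and in 72 of 252 without 1 array. Testing every probe set, which raises the number of tests, ended 20 of these calls (adjusted p up to 0.163), and the replicate block ended those of Tpd52l1, Wt1, Pdk1 and Epcam (0.0533 to 0.0715). Named genes that had not passed gained a call in 19 of 339 and 8 of 234 such fits. Of the 42 called named genes, 21 passed an adjusted p of 0.05 in every alternative fit that tested them, though the filter on the lowest 60% left some of these untested, Rhox5 among them, as did the mean of probe sets for Cacng5 and Hs6st2.

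Leaving out the lowest 60% gave 115 genes higher, 163 changed at least 1.5-fold and 1 list. Testing every probe set gave 135 changed (60 higher, 75 lower, 134 at least 1.5-fold), with 89 of the probe sets used for the 390 genes among them. Median centring, which moved the median of all genes from 0.043 to 0.087, gave 113 lower, and arrayWeights gave 860 changed (410 higher, 450 lower). An adjusted p under 0.01 gave 111 changed (53 higher, 58 lower, 111 at least 1.5-fold) and 1 list, and under 0.1 it gave 728 (388 higher, 340 lower). Camera with estimated correlation passed 0 lists and fry 1. With 1 array left out, 78 to 768 genes changed, 40 to 300 higher, 38 to 468 lower and 78 to 407 at least 1.5-fold. A fit with fewer arrays has less power, yet fits without 1 array ran from 78 to 768 genes, so the number of arrays alone does not set the count. A stricter filter also takes away the calls among the genes it leaves out. The causes of the drops without 1 array were not tested. Nor were those of the rises with arrayWeights and without SCARKO-jsd 2, or of the list counts.

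Direction reversed with arrayWeights for Utp14b (-0.066), H2-Aa (0.055) and Cd74 (0.070), none of them called, and the cause was not tested. With 1 array left out, the log2 fold change lay between -0.078 and 0.246 for Utp14b (negative without SCARKO-jsd 2), -0.361 and 0.074 for H2-Aa and -0.331 and 0.070 for Cd74 (both positive without jsd 3 or SCARKO-jsd 1). The share of calls that were higher was 49.7%, and 57.0% after median centring, 41.7% with the lowest 60% left out, 39.1% without SCARKO-jsd 2 and 62.8% without SCARKO-jsd 1.

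Arrays of the same number deviated together with correlations of -0.21, 0.23 and 0.24 across genes. For every jsd array, the correlation with SCARKO-jsd 2, which stands apart, had the opposite sign to those with SCARKO-jsd 1 and 3. That array may set the pattern, so these correlations cannot decide whether the numbers pair the arrays. Not every array correlated best with its own number (jsd 3 with SCARKO-jsd 1 at 0.35). The replicate block gave 397 genes, 315 of them among the 390. The log2(value + 16) alternative was not run because the values were already log2. Signal over background limits the dim genes, such as Alb.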

Other observations

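The lists of piRNA, synaptonemal, liver, melanocyte and nuclear-retained genes and the tests of germ cell genes were chosen after values were seen, and both tests of the X chromosome pattern were set before their results.

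Single germ cell genes rose in lists chosen to follow up the rises seen, so no list test is given for them. Of 11 tested genes of the piRNA pathway, which silences transposons in the germ line, Piwil2 rose by 1.39 ± 0.23 (SE on the log2 scale), Mael by 1.13 ± 0.18 and Mov10l1 by 0.86 ± 0.11, and the other 8 did not pass the test, with Ddx4 at 1.06 and Asz1 at 0.998. Of 6 tested genes of the synaptonemal complex and meiotic cohesin, Sycp3, Tex12 (0.83 ± 0.11) and Syce3 (0.53 ± 0.11) rose. Tex12 and Syce3 lay under the dim limit in jsd testes (6.36 and 6.47), and 6 of the 12 measured genes of this list were not tested, so its median is not given. The fixed lists hold 1 of the 11 and 3 of the 6 genes.

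Some genes of plasma proteins made by the liver rose, while most of the liver list lay under the dim limit. Ahsg, H2-Q10 and the complement gene Cfi (1.74 ± 0.15 SE) rose, while Ttr, the only other of 16 measured genes bright enough to be tested, did not pass (-0.21 ± 0.10), and the most abundant liver transcript, Alb, read 5.95 in jsd and 5.86 in SCARKO-jsd testes, below the limit of 6.64. The change itself lifted Ahsg and H2-Q10 over that limit (5.69 and 5.39 in jsd testes), so a test of this list as a group shows nothing and is not given. Dct was likewise the only one of 6 tested melanocyte genes to rise, with Tyr at 3.87 and 3.82. None of the 7 tested nuclear-retained RNAs was called, with Neat1 at -0.70 and Malat1 at -0.45 (limma, Benjamini-Hochberg adjusted p = 0.165 and 0.519).

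Among the 30 tested members of the germ cell lists, 5 rose and 2, Id4 and Epcam, fell, with a median of 0.30 and 22 above 0, and of the 3 lists only the meiotic one passed camera at the preset correlation (adjusted p = 0.955 with an estimated correlation). The array that stands apart was argued against as the whole cause of the rises. Uchl1, Dazl, Stra8, Sycp3 and Meig1 were all called without it, as were all 390 genes called with all 6 arrays. The median of the 30 was then 0.244 (95% bootstrap interval 0.047 to 0.557, which treats genes as independent). Lin28a, Sohlh1 and, narrowly, Sohlh2 (6.60, 6.45 and 6.637 in jsd testes, limit 6.642) passed the filter on dim genes only through their SCARKO-jsd level. The 30 thus lean towards rises, and the interval does not speak for the members left out as dim. An equal rise of all germ cells cannot be told apart from a larger rise of later stages, because the median of Stra8 and the meiotic genes exceeded that of 9 of the 16 undifferentiated spermatogonia genes by 0.384 with few genes in each set (9 and 9, with Uchl1, Dazl, Ddx4, Id4, Epcam, Etv5 and Foxo1 left out of the spermatogonia set, two-sided permutation p = 0.598). The genes left out of the spermatogonia set were not taken as restricted to germ cells. A shift in germ cell numbers between the genotypes, or in expression per cell, may underlie the rises and stays untested.

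Changed genes were over-represented on the X chromosome. There 25 of 367 tested genes changed, 7 up and 18 down, or 6.81% against 3.47% elsewhere (odds ratio 2.03, Fisher's exact p = 0.00226, Benjamini-Hochberg adjusted p = 0.0475 over the chromosomes), with Rhox5, Hs6st2, Tsx and Asb9 of smallest p. The changed X genes numbered 10 without jsd 1 (odds ratio 4.30), 14 without jsd 2 (3.93), 12 without SCARKO-jsd 3 (2.72) and 40 without SCARKO-jsd 2 (1.65), with Fisher's exact p from 4.54e-05 to 0.00496 over all arrays left out in turn. Weakly read genes were argued against as the whole cause, since an excess remained with the lowest 60% left out. The odds ratio was then 1.81 (Fisher's exact p = 0.0302, not adjusted over the chromosomes). Strain variants on the X chromosome could also place changed genes side by side, and 2 adjacent pairs were found where random draws gave a median of 1 (share of draws 0.4997), too few to decide.

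Of the 134 symbol families, 0 passed camera at a Benjamini-Hochberg adjusted p under 0.05 and 6 had an unadjusted p under 0.05, the lowest adjusted p being 0.268 for Akap and Tex.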
